A study of Drosophila melanogaster with 3 samples.

How the data were processed

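Chromatin immunoprecipitation and sequencing was performed, per the labels, on whole Drosophila melanogaster embryos of mixed sex aged 0 to 16 h. The flies carried a transgene in which GFP was fused to the C terminus of CG18764, and an antibody against GFP was used. Chromatin was sonicated, with a size range of 200 to 800 bp per the labels. The 3 samples are biological replicates of 1 group, per the labels, so no comparison between groups was made. No control samples are part of the data used here.

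The authors deposited peak lists in the narrowPeak layout on the dm6 and dm3 builds. Per the labels and the deposited file listing, each replicate has a relaxed list of peaks and background that served as input to the irreproducible discovery rate procedure. A relaxed list from the pooled replicates and an optimal list after thresholding were deposited as well. All were called against 1 control dataset shared by the replicates, per the deposited file listing. The aligner, peak caller, their versions and the thresholds are not given in the sources used here. Sequencing depth is unknown, and no interval that needs it is given.

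The deposited signal value of each peak is a score with no stated scale. It is the authors' value and was used only to rank and filter peaks within a list. The deposited −log10 q value was at its maximum in 3449 of the 3754 optimal dm6 peaks and was not used for ranking. The deposited summit offset, in bp from the peak start, gave each summit. The dm6 optimal list was identical to the 3754 highest peaks of the pooled relaxed list by signal.

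Coordinates are 1-based on dm6, which is assembly release 6. Gene models were taken from Ensembl release 115, with 18277 genes and 23694 distinct transcription start site (TSS) positions on the main arms, and sequence came from the matching reference assembly. No dm3 sequence or annotation was used here, and no coordinate was converted between builds. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

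Peaks were counted as shared when their summits lay within 100 bp. Each replicate list was taken to its 3754 highest peaks, the number of optimal peaks. Overlap between replicates was tested against 1000 random placements within chromosomes, one-sided. Promoter peaks had a summit within 500 bp of a TSS and were tested against 10000 random placements on assembled bases, two-sided. Because placements are independent, they were drawn as binomial counts from the share of each arm's bases near a TSS. Other summits were assigned in the order 5′ UTR, 3′ UTR, coding exon, noncoding exon, intron and intergenic. The order fixed before the data were examined placed introns ahead of noncoding exons; this departure can move at most 33 peaks. Peaks per chromosome arm were compared with the arm's share of non-N bases by two-sided exact binomial tests with Benjamini-Hochberg adjustment.

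A total of 23 gene lists were fixed before the data were examined. Genes with a promoter peak were compared inside and outside each list by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the lists. Lists of protein-coding genes were set against other protein-coding genes, and the tRNA, snRNA and histone lists against all genes. In total 4 listed symbols had no match in the annotation. Genes with a promoter peak include those that share a peak with a neighbour.

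Sequences were counted in the central 100 bp around each summit and in a 100 bp window centred 300 bp away, on alternating sides. The 2080 6-mers, the 32896 8-mers (each merged with its reverse complement) and 19 consensus sequences fixed before the data were examined were compared by two-sided exact McNemar tests, adjusted within each family. Divergent promoters were protein-coding TSS with an opposite-strand TSS upstream within 1000 bp, tested against 10000 random draws of TSS. These draws do not allow for a summit that reaches both TSS of a pair, so summits were also placed at random TSS at the observed offsets, 1000 times, counting every TSS in reach. Spacing was the share of peaks with another optimal summit within 5000 bp, tested against 1000 placements. Tests across peaks or genes treat positions in 1 merged list as units; they do not measure variation between embryo collections.

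The methods were tested on simulated data. Of 20 random peak sets, 2 were called for promoter share and 0 for spacing. A planted promoter share of 36.6% was returned as 37.2%. At random positions, 0 of 19 consensus sequences, 1 of 2080 6-mers and 0 of 32896 8-mers were called, and a planted 8-mer ranked 1 of 32896. Random positions lack the lower GC content that summits had against their flanks, so these counts do not cover it. Over random gene sets 0 of 460 list tests were called, and a planted list was recovered in 20 of 20 runs. These sets drew genes independently, so they do not cover neighbouring genes that share a peak.

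Genes were named by a rule fixed before the data were examined: the nearest gene of each of the 25 highest optimal peaks, up to 4 members of a discussed list with a promoter peak by signal and up to 2 without, the 5 genes with most peaks, and CG18764 with its surroundings. A gene that this rule selects is not reported here. Named sequences were the 10 6-mers and 10 8-mers of lowest p and every fixed consensus.

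Alternative settings fixed before the data were examined were summit distances of 50 and 250 bp, a reciprocal overlap of 50%, fewer and more replicate peaks, the dm3 lists, a stricter optimal list, peaks found in all 3 replicates, and leaving out each replicate. For replicate recovery and overlap, the replicate's list was dropped. For all other results, the optimal peaks found among the highest peaks of both other replicates were kept, because no list without that replicate was deposited; this also shortens the list. Others changed the TSS distance to 250 or 1000 bp, the random background, the gene background, the windows, the pair distance to 500 bp and the spacing to 2000 or 10000 bp. Chosen after seeing the data were a dinucleotide shuffle as sequence control, TSS merged to loci, summits placed at random TSS, an expectation without Y, and the removal of peaks absent from the relaxed list of replicate 1.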

Results

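Binding of CG18764, a zinc-finger protein of the ZAD class, was mapped in whole embryos aged 0 to 16 h with a GFP fusion and an anti-GFP antibody. The 3 biological replicates form 1 group. The optimal list held 3754 peaks on dm6, with a median width of 400 bp. Each replicate's relaxed list held 30000 peaks, and the number of reads behind them is unknown.

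The strongest sites lay at promoters and ranked high in every replicate. The 2 highest peaks were both at gus, which encodes a SOCS-box protein. Their summits were at 2R:5128371 and 2R:5122312, at −50 and −65 bp from a TSS (negative upstream). The first ranked 1 in all 3 replicates, and the second had a mean rank of 3 ± 1.73 (SD, n = 3). CG3253 at 2R:24114352 (mean rank 3 ± 1), the UDP-galactose transporter gene Ugalt at X:2703885 (4 ± 1) and CG14100 at 3L:19590621 (4 ± 1) followed.

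Of the 25 highest peaks, 22 had a summit within 500 bp of a TSS and 16 within 100 bp, and none ranked below 31 in any replicate. Their nearest genes included regulators of chromatin and transcription, among them Chro, the histone acetyltransferase gene enok, the Polycomb group gene ph-p and the neural zinc-finger gene scrt. Genes of translation and RNA turnover were eIF2Balpha, mRpL41 and Smg5. The genes Vps13D, px, Art3, DUBAI, CG1233, CG9915, CG1888, CG8617 and lncRNA:CR31840 also had promoter summits. The other 3 summits were intronic, nearest to cbt (−1370 bp from its TSS), CG11050 (1035 bp) and the kinase gene Lk6 (−971 bp).

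Several long genes held many peaks. The noncoding gene lncRNA:CR44357 held 16, the gene CG1677 that overlaps it held 13, and kirre, which acts in myoblast fusion, held 12 over 394 kb. The genes sbb and ush held 11 each. Per 100 kb these were 6.66, 10.3, 3.04, 13.7 and 16.8 peaks, against 2.74 over all assembled bases, so kirre was close to the overall density.

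The CG18764 gene (FBgn0042205, 3R:11626889 to 11628452) had no promoter peak. The strongest optimal peak within 20 kb was at 3R:11623193, at −3696 bp from the gene start, and ranked 88. Its nearest TSS, 96 bp away, was that of Zaf1. Replicates 2 and 3 each ranked this site 90. Replicate 1 had no peak there: its highest peak within 20 kb was at 3R:11616547 and ranked 2924. Further optimal peaks ranked 930 and 1686 and lay at −6883 and −13569 bp from the gene start. Another at 3R:11628623, ranked 2413, lay 1734 bp downstream of the gene start.

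Most optimal peaks were recovered in each replicate. Among the 3754 highest peaks of replicates 1, 2 and 3, 74.96%, 83.9% and 80.4% of the optimal peaks were found, a mean of 79.8% ± 4.53 (SD, n = 3). The optimal list is the top of a pooled list built from the same replicates, so a high recovery follows in part from its construction. All 3 replicates held 2132 optimal peaks, 1024 were in 2 replicates, 541 in 1 and 57 in none. In the whole relaxed lists, 91.6%, 96.7% and 96.9% were found.

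**Figure D1:**
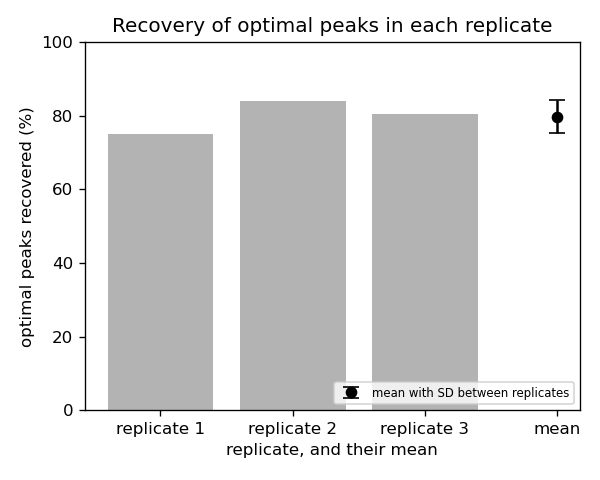
Percentage of the 3754 optimal peaks with a summit within 100 bp of one of the 3754 highest peaks of each replicate (bars), and the mean with its SD over the 3 replicates (point). Replicate 1 was lowest at 74.96% and replicate 2 highest at 83.9%.

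Pairs of replicates shared much of their lists. The shared percentage was 65.4% for replicates 1 and 2, 63.7% for 1 and 3, and 71.7% for 2 and 3, against chance means of 0.561%, 0.568% and 0.563%. Each pair had a one-sided permutation p of 0.001, adjusted p 0.001, the smallest that 1000 placements can give. Across peaks, which are not independent replicates, Spearman's rho of the ranks was 0.72, 0.73 and 0.76. No peak was identical in both position and signal value between replicate lists.

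Promoters held 1991 of the optimal peaks, 53.0% (Wilson 95% interval 51.4 to 54.6%). Random placement gave 13.6%, a 3.90-fold difference (two-sided permutation p = 0.0002, the smallest the placements can give). Coding exons held 8 peaks, 0.213% against 13.1% at random, and 3′ UTRs held 26, 0.693% against 5.05%. Introns held 1213 peaks (32.3% against 39.5%), intergenic sequence 461 (12.3% against 27.2%), noncoding exons 33 and 5′ UTRs 22.

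Promoter summits lay on the upstream side. Of the 1991, 84.1% were upstream of the TSS, with a median position of −104 bp and quartiles of −187 and −38 bp. The promoter percentage was 67.4% in the 500 highest optimal peaks and 44.6% in the 500 lowest. A promoter peak was present at 2502 of 13968 protein-coding genes (17.9%) and at 164 of 3289 noncoding RNA genes (4.99%).

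**Figure D2:**
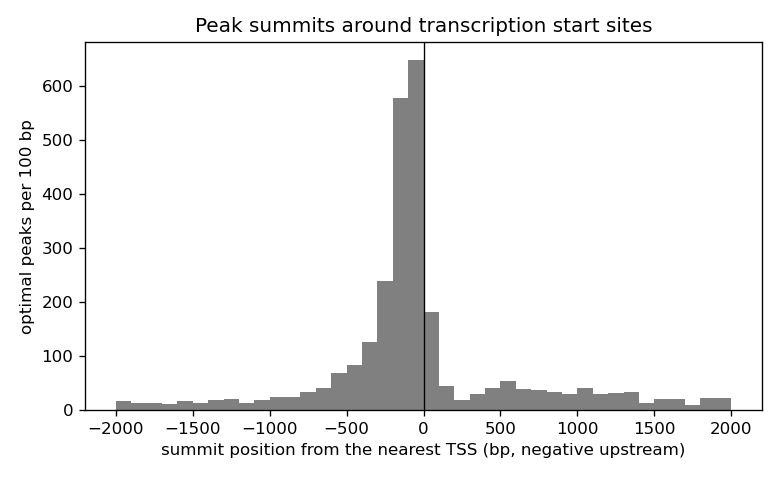
Number of optimal peak summits per 100 bp (vertical axis) by position from the nearest TSS in bp (horizontal axis, negative upstream). The tallest bar, with 649 peaks, covers the first 100 bp upstream.

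TSS with a peak were often divergent. Of 3079 protein-coding TSS with a summit within 500 bp, 61.0% had an opposite-strand TSS upstream within 1000 bp, against 31.3% of all 19276. One summit can reach both TSS of a divergent pair, so summits were also placed at random TSS at the observed offsets, a choice made after seeing the data. This gave 44.4% ± 1.16 (SD over placements; two-sided permutation p = 0.002, the smallest the placements can give). The peak at 3R:15229535 lay at −127 bp from the TSS of Art3 and −130 bp from that of mRpS10. Merging neighbouring TSS to loci, a choice made after seeing the data, gave 47.5% of 1765 loci against 18.7%. A locus counted as divergent, and as having a peak, if any of its TSS did. Loci with more TSS can thus be both more often, which this comparison does not allow for.

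Peaks lay near one another. Within 5000 bp of another optimal summit were 49.3% of the peaks, against 24.6% at random (two-sided permutation p = 0.002, the smallest the placements can give). Random choice of TSS positions in place of random bases gave 41.0%.

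Genes for cytosolic ribosomal proteins stood out among the lists. A promoter peak was present at 61 of 85 (71.8%) against 17.6% of other protein-coding genes (Fisher's exact test, adjusted p = 3.3e-26). RpS27 (rank 74), RpL7 (102), RpL41 (201) and RpL32 (216) had the highest peaks, and RpS19b and RpL10Aa had none. Mitochondrial ribosomal protein genes had a peak at 23 of 73 (31.5% against 17.8%, Fisher's exact adjusted p = 0.017), among them mRpS10 (rank 10), mRpL41 (17), mRpS23 (29) and mRpL23 (49), while mRpS21 and mRpL11 had none.

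General transcription genes also had more promoter peaks than other genes, at 14 of 35 (40.0%, Fisher's exact adjusted p = 0.016), with Polr2B (rank 348) and Polr2H (449). Another 3 lists passed in the whole optimal list but not in every smaller set of peaks below, and the same held for mitochondrial ribosomal proteins. The Polycomb and trithorax list had 9 of 20 (45.0%, Fisher's exact adjusted p = 0.017), with ph-p (rank 22), brm (144), Su(z)12 (300) and E(z) (586). Insulator and architectural protein genes had 8 of 19 (42.1%, Fisher's exact adjusted p = 0.035), with Chro (11), pzg (111), Cp190 (187) and Trl (765), and no peak at CTCF or su(Hw). Cell cycle genes had 9 of 20 (45.0%, Fisher's exact adjusted p = 0.017), with CycD (857) and Dp (1116), and no peak at CycA or CycB.

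Of these 6 lists, only cytosolic ribosomal proteins stayed past the threshold when genes with a relaxed pooled peak were the background. Their odds ratio was then 6.03, against 11.9 in the main test, with a promoter peak at 36.0% of the other genes. Settings without a replicate kept only optimal peaks found in both others (2624, 2358 and 2438 peaks without replicates 1, 2 and 3), so the replicate and the number of peaks changed together. Cytosolic ribosomal proteins and general transcription passed in all 3 sets. The insulator list passed in none (odds ratios 2.36, 3.39 and 3.27, against 3.34 in the whole list), nor did the cell cycle list (1.65, 3.15 and 2.36, against 3.76). The Polycomb and trithorax list passed only without replicate 3 (odds ratios 2.21, 3.15 and 3.82, against 3.76), and mitochondrial ribosomal proteins only without replicate 1 (2.17, 1.75 and 1.68, against 2.12). Lost calls with odds ratios near those of the whole list had fewer peaks to count, and no loss was traced to a replicate.

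Genes for tRNA had fewer promoter peaks, at 10 of 295 (3.39% against 14.95% of other genes, Fisher's exact adjusted p = 1.7e-09). These other genes are mostly protein-coding (13968 of the 18277 genes). Noncoding RNA genes (4.99%) and snoRNA genes (4.46%) were also low, while snRNA genes were at 15.6% (5 of 32). The snRNA count was 4 without replicate 1. It was 0 in the stronger peaks, in peaks of all 3 replicates, and without replicate 2 or 3. A low share is therefore not particular to tRNA genes. None of the 111 replication-dependent histone genes had a promoter peak. They are repeated copies and none had even a relaxed pooled peak, so whether peaks can be called there is unknown and their test was not interpreted.

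The other 15 lists did not pass the threshold. Hox genes had 0 of 8 and segmentation genes 1 of 19, at bcd (rank 1279). Germline genes had 5 of 11, with bgcn (247) and orb (367), at a Fisher's exact adjusted p of 0.084, and passed without replicate 1 (0.035). ZAD zinc-finger genes had 5 of 19, Notch pathway genes 6 of 17, oxidative phosphorylation genes 17 of 80, proteasome genes 6 of 48, snRNA genes 5 of 32, and heat shock genes 4 of 15, with Hsp27 (121) and Hsp83 (257). Heterochromatin genes had 4 of 14, gut, fat body and hemocyte genes 3 of 12, dorsoventral genes 2 of 14, nervous system genes 2 of 15, muscle genes 2 of 15 and dosage compensation genes 1 of 7.

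**Figure D3:**
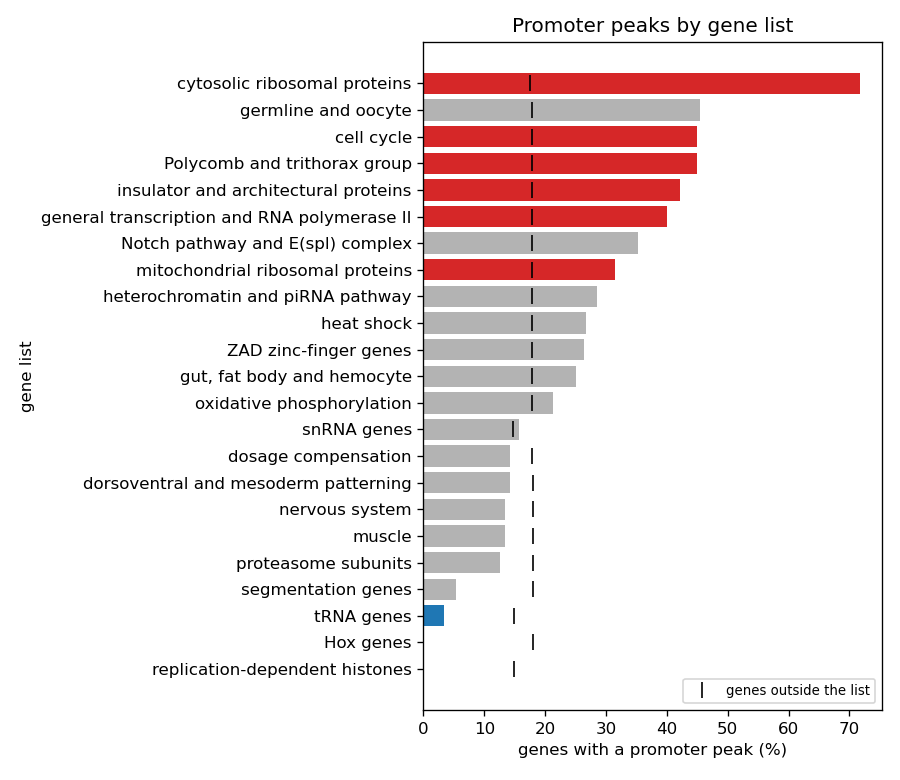
Percentage of genes with a promoter peak in each of the 23 lists (bars) and among genes outside it (ticks). Red bars are higher and blue lower at an adjusted p under 0.05, and grey bars did not pass; histones, whose test was not interpreted, are at 0.

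Peak summits were rich in A and T. Mean GC content was 33.8% ± 8.90 (SD across peaks) in the central 100 bp and 43.7% ± 9.92 in the flank, and it was lower at the centre in 2808 peaks and higher in 869. Of the 6-mers, 465 were higher at the summit and 896 lower. The 10 of lowest p were TAAATA, AAATAT, TTAAAA, ATTTAA, ATTTTA, ATATTA, AATATA, TATTAA, ATTAAA and AAAATA, and TAAATA was in 1129 centres against 472 flanks. Of the 8-mers, 819 were higher and 613 lower. Lowest in p were ATTTAAAA (237 centres against 65 flanks), AAATAATT, AAATATAT, ATATTTAA, ATTTAATA, TAATATAA, ATATTAAA, TTTAAAAA, ATTTTAAA and AAATAAAT.

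**Figure D4:**
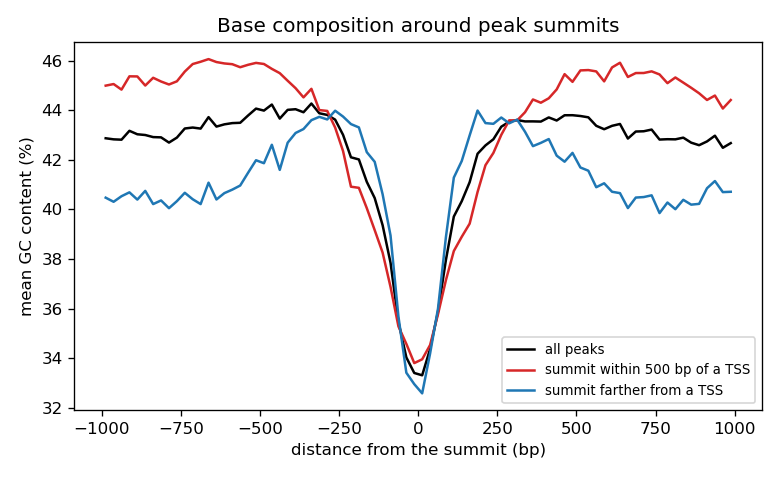
Mean GC content in percent (vertical axis) by distance from the summit in bp (horizontal axis) for all optimal peaks, those within 500 bp of a TSS and the others. All lines dip at the summit, where the central 100 bp averaged 33.8% over all peaks.

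Known promoter and insulator sequences were among the 6 fixed consensuses higher at summits. The DRE sequence TATCGATA was in 83 centres against 13 flanks (exact McNemar adjusted p = 5.0e-14), and its core CGATA, bound by BEAF-32, in 650 against 443. Away from TSS, DRE (5 against 1), CGATA (175 against 180) and the Su(Hw) core (25 against 15) were not called (exact McNemar adjusted p = 0.320, 1 and 0.266). The Su(Hw) core was in 1.42% of peaks away from TSS and 1.10% of promoter peaks (Fisher's exact adjusted p = 0.515), so its share was not higher at promoters. Over all peaks the Su(Hw) core was in 47 against 16, the TATA box in 314 against 129, the GATA site in 794 against 589 and the Hox core TAATTA in 372 against 217. Lower were the GAGA repeat (352 against 589), the longer GA tract (18 against 64), the E-boxes CAGCTG (119 against 180) and CACATG (113 against 186), and the CA repeat (41 against 149). CAGCTG was not called in peaks of all 3 replicates (exact McNemar adjusted p = 0.267), nor without replicate 1 (0.063) or 3 (0.090).

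The other 8 consensuses did not pass over all peaks: the Zelda site (19 against 20), the M1BP motif (25 against 14), the CTCF core (161 against 149), CACGTG (31 against 51), the Initiator (917 against 855), the Bicoid core (129 against 110), AP-1 (35 against 31) and the A tract (251 against 218). In promoter peaks alone, the M1BP motif (23 against 9), the CTCF core (91 against 59) and the A tract (124 against 89) passed (exact McNemar adjusted p = 0.032, 0.019 and 0.032). CAGCTG (76 against 91), lower over all peaks, was not called there (exact McNemar adjusted p = 0.276). Against a dinucleotide shuffle of the same window, a control chosen after seeing the data, GAGA, CAGCTG and the CA repeat were higher, the GATA site was lower and the TATA box and TAATTA were not called. The CTCF core (161 centres against 60 shuffles) and the M1BP motif (25 against 0) were higher in that comparison. The DRE sequence was in 3.92% of promoter peaks and 0.284% of the others (Fisher's exact adjusted p = 1.5e-15). The M1BP motif differed in the same direction (1.16% against 0.113%, Fisher's exact adjusted p = 2.6e-04). The CTCF core (4.57% against 3.97%) and the A tract (6.23% against 7.20%) did not differ by this test (Fisher's exact adjusted p = 0.475 and 0.343). Their calls in promoter peaks alone thus do not make them particular to promoters.

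Peaks were spread over the major arms. Chromosome 4 held 19 peaks where its assembled bases gave 36.5, a ratio of 0.52 (exact binomial adjusted p = 0.0070). The ratio was 0.34 to 0.44 without a replicate, and the pooled relaxed list held 557 peaks there (1.86%). Y held 0 where 93.4 were given. The pooled relaxed list held only 1 peak on Y, so whether peaks can be called there is unknown and this 0 was not interpreted. The ratios of X, 2L, 2R, 3L and 3R were 1.00, 1.08, 0.97, 1.04 and 1.05, none past the threshold. With Y left out of the expectation, they were 0.978, 1.06, 0.949, 1.01 and 1.02, again none past the threshold. Without replicate 3, 2L (1.10) and 2R (0.90) passed it (exact binomial adjusted p = 0.036 each), and 2L did in the stronger peaks (1.13, exact adjusted p = 0.030). With TSS positions as the expectation, chromosome 4 was at 0.66 (adjusted p = 0.087), 2L at 0.957 (adjusted p = 0.234), 2R at 0.87 (adjusted p = 2.4e-04) and 3L at 1.11 (adjusted p = 0.0033), by the same exact test.

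The dm3 optimal list held 3645 peaks against 3754 on dm6. Its relaxed lists held 27745 peaks for replicate 1 and 30000 for each of the others.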

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

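Tests chosen after the result was seen are those of the CG18764 locus, graded enrichment, the GC content of promoters, the 8-mers left over from the shuffle and other housekeeping genes. Outliers were not sought, because the group has 3 samples.

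Peaks on heterochromatic and unplaced dm3 scaffolds, which entered only the dm3 totals, exceeded the 3 peaks taken as the limit. There were 730 in the relaxed list of replicate 1 (2.63%), 97 in replicate 2 (0.323%), 72 in replicate 3 (0.240%), 188 in the pooled relaxed list (0.627%) and 4 in the optimal list, all 4 on 3LHet.

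A few strong sites were missing from single replicates. Sites among the 1000 highest of both other replicates numbered 803 for replicate 1, 757 for replicate 2 and 754 for replicate 3. Of these, 10 had no peak within 500 bp in replicate 1, including those nearest Zaf1, CG3792, Lamtor3, Taf5 and RpL11. In replicate 2, 5 had none, including RpL14, Sptz and EMC6, and in replicate 3, 0 had none (genes named after their values were seen). A genotype difference at the CG18764 locus is argued against for 14 of the 15, which lay over 20 kb away; for the 1 within 20 kb it stays open, since a single site cannot be told apart from the rest of the missing sites. Graded weaker enrichment stays open for all 15. Among the 500 highest, 7 sites were missing (3 of 417 in replicate 1 and 4 of 390 in replicate 2) and 0 were beyond rank 3754. The missing share of these affected sites was 100% (exact 95% interval 59.0 to 100%). This share cannot decide the question. It counts only sites already missing or beyond that rank, pools replicates 1 and 2, and was chosen after the result was seen. Among the 1000 highest and not the 500 highest, 8 sites were missing and 6 were beyond that rank (5 in replicate 1, 0 in replicate 2 and 1 in replicate 3). The missing share was 57.1% there (exact 28.9 to 82.3%), and 71.4% over all 21 sites (exact 47.8 to 88.7%). Filtering by the caller was not tested, and no biological explanation was tested.

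Sequences rich in A and T marked summits. Base and dinucleotide composition alone is argued against for 65 of the 819 8-mers, which were also higher than in a shuffle of the same window. They included TATCGATA, ATCGATAG and CAACACTG (66 centres against 9 shuffles). The 65 were 7.94% (Wilson 95% interval 6.28 to 9.99%), above the 5% set before the shuffle was run, though not by much. That limit is not the share expected under composition alone, so the margin over it does not measure the evidence. The interval treats 8-mers as independent, although some overlap, such as TATCGATA and ATCGATAG. Of the 65, 16 held only A and T, such as AAATATAT (224 centres, 2.22 times its shuffles) and AATAAATA (253 against 132), as did 131 of the 819. Only these 16 bear directly on sequences made of A and T. For the other 754 8-mers composition cannot be told apart, because they were not called against the shuffle. The low GC of promoters is argued against for the 1763 peaks over 500 bp from a TSS. Their GC content dropped by 10.3 percentage points ± 0.322 (SE across peaks) from flank to centre. The 1991 promoter peaks dropped by 9.55 points ± 0.346. For them this explanation stays open, because peaks elsewhere cannot decide it.

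Promoter peaks at ribosomal protein genes were weighed against 3 explanations. A general preference for housekeeping genes stays open. Oxidative phosphorylation genes without paralogues, by symbol, had a peak at 17 of 59 (28.8%), with a Wilson upper bound of 41.4%, above 35.9%, which is 50% of the ribosomal share. The ribosomal list kept its paralogues, so these shares do not compare like with like. With all members, the upper bounds were 31.4% for oxidative phosphorylation and 24.7% for proteasome genes, below 35.9%. The answer thus depends on whether paralogues are counted. Proteasome genes without paralogues had 6 of 32 (18.8%, upper bound 35.3%), while general transcription was at 40.0%, and expression itself was not analysed here. The number of TSS positions and a divergent neighbouring promoter are argued against. Among 10000 lists matched on the number of TSS positions, 0% reached 71.8% (mean 20.9% ± 4.29, SD), and among lists matched on a divergent neighbouring promoter 0% did (mean 23.3% ± 4.44), with a highest of 43.5%. Antibody and chromatin artifacts at active promoters stay open, as no control samples were analysed here.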

How the results depend on the processing

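Chosen after seeing the data were the shuffle control, merged loci, summits placed at random TSS, the expectation without Y and the removal of peaks absent from replicate 1. Depth is unknown, so its effect on weak peaks could not be examined. Replicate overlap, promoter share, divergent promoters and peak spacing kept their direction and side of the threshold under every alternative run; promoter share ranged from 42.7% to 63.3%. No paired analysis was possible because there is 1 group. The cause of each change below was not tested, except that smaller peak sets and lists leave fewer peaks to test. Settings without a replicate are such smaller sets (2358 to 2624 peaks, found in both other replicates), except for recovery and overlap.

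Mean recovery was 71.2% with summits within 50 bp, 70.0% with reciprocal overlap, and 91.8% with longer replicate lists. With shorter replicate lists it was 48.2%, where list length alone set a limit of about 50%. On 2L the ratio was 1.13 in the stronger peaks and 1.08 to 1.10 without a replicate, and it turned to 0.957 against TSS positions, though not called; on 2R it was 0.87 against TSS positions and 0.90 to 1.00 without a replicate; 3L was 1.11 and chromosome 4 0.66 against TSS positions. Lists higher numbered 6, against 2 in the stronger peaks, 2 in peaks of all 3 replicates, 2 to 4 without a replicate and 1 with the relaxed background, where lists lower were 1 and histones gave no value. The 4, without replicate 1, were cytosolic and mitochondrial ribosomal proteins, general transcription and germline, which was not among the 6. The cell cycle list was also lost at a TSS distance of 250 bp (25%), and mitochondrial ribosomal proteins at 1000 bp (Fisher's exact adjusted p = 0.082).

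Fixed consensuses higher were 3 away from TSS, and those lower were 2 against the shuffle. Against the shuffle 173 6-mers were higher and 216 lower. The 8-mers higher numbered 254 in the stronger peaks, 357 in peaks of all 3 replicates, 387 to 513 without a replicate, 185 in 50 bp windows, 196 away from TSS and 118 against the shuffle; those lower numbered 70, 149, 170 to 238, 43, 53 and 13. Directions reversed against the shuffle for GAGA (9.38% against 6.23%), the GA tract (0.479% against 0.213%), CAGCTG (3.17% against 1.41%), GATA (21.2% against 23.6%), the CA repeat (1.09% against 0.453%) and TAATTA (9.91% against 11.1%), and away from TSS for CGATA (9.93% against 10.2%); the GA tract, TAATTA and CGATA were not called in these (exact McNemar adjusted p = 0.113, 0.113 and 1). Of the other tested values for single lists and sequences, 139 were the same and 32 no longer passed. Mean ranks of single peaks without a replicate were left out of these counts: with 3 values such a mean cannot move by the spread, so they do not speak to stability.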

Other observations

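The tests of symbol families were set before their own results were seen, but after the main results. Of 42 families of at least 15 protein-coding genes that share a symbol prefix, 18 differed from other genes in their share with a promoter peak (Fisher's exact test, Benjamini-Hochberg adjusted), 9 higher and 9 lower. Besides the prefixes RpL, RpS and mRpL, 6 were higher by the same exact test: PIG genes of GPI anchor synthesis had 10 of 21 (47.6%, adjusted p = 0.0072), peroxisomal Pex genes 8 of 15 (53.3%, adjusted p = 0.0078), Sec genes 8 of 19 (42.1%, adjusted p = 0.036), autophagy Atg genes 8 of 20 (40.0%, adjusted p = 0.042), Vps genes 10 of 27 (37.0%, adjusted p = 0.045) and the prefix pre 10 of 24. Rab (9 of 31), Vha (6 of 22), Nup (6 of 21) and mRpS (7 of 26) did not pass. The prefix pre stands almost wholly for gene models of the mod(mdg4) locus and is not an independent family.

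Families of sensory and cuticle genes were among the 9 that were lower. Gustatory receptor genes had 0 of 60 and odorant receptor genes 0 of 59, ionotropic receptor genes 1 of 60, odorant binding protein genes 1 of 51, cuticle Cpr genes 1 of 71, Osi genes 0 of 25, cytochrome P450 genes 2 of 85, Ugt genes 1 of 35 and histone-prefix His genes, mostly repeated copies where peak calling is uncertain, 2.61%, against about 18.0% of other genes. Many of these genes lie in clusters, so their members are not independent.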
